A study of Mus musculus with 4 samples.

How the data were processed

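Total RNA of 4 mouse MSC lines, 2 from colon and 2 from bone marrow, was amplified, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. Cells were grown in low-glucose medium with 10% serum and lysed between passages 5 and 10, per the series design text. The deposited values are probe set intensities on a linear scale, as judged from the values themselves, which carry decimals and are never negative. The algorithm the authors used to summarise probes, the background correction and any scaling between arrays are not given in the sources used here. The 4 arrays have log2 medians within 0.04 of each other, so the values had been scaled, or came out alike, before deposit. Intensities have no fixed unit, and those of different probe sets are not compared as amounts. No detection call was used, so a low intensity is described as near the floor and not as absence.

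All choices of test, filter, gene list and alternative were fixed before the data were examined unless stated otherwise. Values were transformed as log2(intensity + 13.7), the pseudocount being 0.25 of the median of all values (54.6), and the deposited scaling was kept because the array medians lay within the preset limit of 0.5. A log2 difference on this scale understates the ratio of intensities for genes near the floor, and a difference of 1 corresponds to 2-fold only for bright genes. Of the probe sets, 64 were array controls and were left out, 34945 were paired with 1 gene symbol by the platform annotation, 932 with several and 9160 with none. Only probe sets with 1 symbol were named, which covered 18193 genes, and members of the gene lists without such a probe set are not analysed here. Probe sets passed the filter when their mean over the 4 arrays exceeded the 40th percentile, an intensity of about 31.9. A gene near the floor in 1 tissue could thus pass through the other tissue alone, which favours genes that differ. The probe set with the highest mean stood for its gene, which left 12920 genes. In 5975 genes more than 1 probe set passed the filter, and in 0 of these did probe sets differ between tissues by at least 2-fold in opposite directions. Current symbols of 2 list members were matched to the older symbol in the annotation.

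Tissues were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend on all 4 arrays, with the tissue as the only term and the contrast colonic minus bone marrow. P-values are two-sided and were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior of 2.53. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, since 3 divisions of the arrays exist, so none is printed for single genes. Standard errors are those of limma, and standard deviations are over the 2 intensities of a tissue.

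The 27 gene lists name markers, pathways and transcription factor families that fit the tissues, and 25 of them, with at least 5 measured members, were tested as sets with limma's camera at its preset correlation of 0.01, adjusted over the 25 lists. Camera asks whether a list ranks higher or lower than the other genes. It was repeated with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way, was run beside it. The estimated correlation rests on the 2 residual degrees of freedom, which leaves that form of camera little power. A list that does not pass it is therefore not shown to be unchanged. Named genes were the 12 in each direction with the largest difference among those past the threshold, with places left open going to the lowest unadjusted p, so that here all 24 were placed by p and did not pass, then up to 4 members of each list in the order of their p, Ptgs2 and Igf2bp1 as genes known from colonic MSC, and the sex-linked genes. Members named beyond these, such as Itgav, Lyz2, Acta2, Cnn1, Des, Myh11, Cxcl12, Tbxas1, Ptges, Col6a3, Col1a2, Col4a1, B2m, H2-D1, H2-K1, Ndn, Hmga2, Mki67, Cdk1 and Cdkn1a, were chosen after their values were seen.

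Alternatives were quantile normalization, median centring, pseudocounts of 1 and of the table median, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, a fit without the trend, a robust fit, the replicate number as a block, each probe set tested separately, an adjusted p of 0.1, and each array left out in turn, where the lone array of a tissue is assumed to vary like the other tissue. The procedure was tested on simulated data made from the 12920 genes in 20 draws with 200 changed genes each. At an adjusted p below 0.05, 25.1% of genes changed by 2 on the log2 scale were recovered, 67.7% of those changed by 4 and 82.7% of those changed by 6, and a shifted list ranked first in 20 of 20 draws. Of the genes below an adjusted p of 0.1, 8.15% were unchanged ones. Values were drawn independently for each gene and array. The simulation therefore does not cover genes that vary together within a line, on which the list tests depend. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.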

Results

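Mesenchymal stem cells (MSC) are plastic-adherent stromal cells that can be led to form bone, fat and cartilage. Lines of such cells from the colon and from the bone marrow of C57BL/6 mice were profiled on Affymetrix mouse expression arrays, 1 array per line, with 2 colonic and 2 bone marrow lines. The median intensity lay between 53.7 and 55.7 and the upper quartile between 611 and 657 on the 4 arrays. Across all probe sets, which are not independent replicates, log2 intensities of the lines of 1 tissue correlated with r = 0.973 (bone marrow) and r = 0.967 (colon), and those of lines from different tissues with r between 0.953 and 0.970. The labels call the arrays biological replicates, and the number of arrays limits the precision of every value.

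The comparison asks in which transcripts colonic MSC differ from bone marrow MSC grown in the same medium. Both colonic lines had strong signals for a set of genes that lay near the floor in both bone marrow lines. Thy1, the surface glycoprotein CD90, had an intensity of 27.4 ± 7.63 (SD, n = 2) in bone marrow and 6774 ± 3193 (SD, n = 2) in colonic MSC, a log2 difference of 7.30 ± 0.47 (SE). Meg3, an imprinted noncoding RNA, stood at 44.1 ± 0.962 (SD, n = 2) against 9178 ± 3022 (SD, n = 2), a log2 difference of 7.27 ± 0.37 (SE). Genes lower in both colonic lines included the homeobox gene Pitx1, at 2154 ± 245 (SD, n = 2) in bone marrow and 36.8 ± 12.9 (SD, n = 2) in colon, and Adamtsl3, a secreted matrix protein gene, at 4108 ± 295 (SD, n = 2) and 55.4 ± 21.1 (SD, n = 2).

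Among the 12 genes with the lowest p toward colon were also Cyba, a subunit of the phagocyte NADPH oxidase, with a log2 difference of 6.67 ± 0.37 (SE), and Plac8, with 6.65 ± 0.46 (SE). The insulin-like growth factor binding proteins Igfbp6 and Igfbp2 differed by 6.51 ± 0.42 and 6.38 ± 0.34 (SE), and Rian, a noncoding RNA next to Meg3, by 6.42 ± 0.41 (SE). Ptgis, the prostacyclin synthase, had intensities of 3602 and 3661 in the colonic lines and 68.0 and 62.6 in the bone marrow lines. The transcription factor gene Hoxb2 (5.33), Klhl29 (5.20), Nipal4 (4.84) and Sprr1a, a cornified envelope protein gene (4.82), completed those 12, with the log2 differences given. Among the 12 genes with the lowest p toward bone marrow, Gpm6b, a membrane glycoprotein gene, had a log2 difference of -5.51 ± 0.32 (SE). In the same 12 were the acute phase protein gene Hp (-4.37), the adipogenic transcription factor gene Cebpa (-4.26), Kirrel3 (-4.25), Rnf144a (-4.20), Shisa2 (-3.96), Sned1 (-3.44), the osteogenic homeobox gene Dlx5 (-3.15), Tafa1 (-2.88) and Col6a1 (-2.05), all on the log2 scale. Other probe sets of some of these genes differed less, at -0.05 for Rnf144a, -3.48 for Gpm6b, 1.55 for Nipal4 and 2.80 for Rian. Col6a1, a collagen VI chain, was at 8227 ± 345 (SD, n = 2) in bone marrow and 1983 ± 107 (SD, n = 2) in colon.

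**Figure D1:**
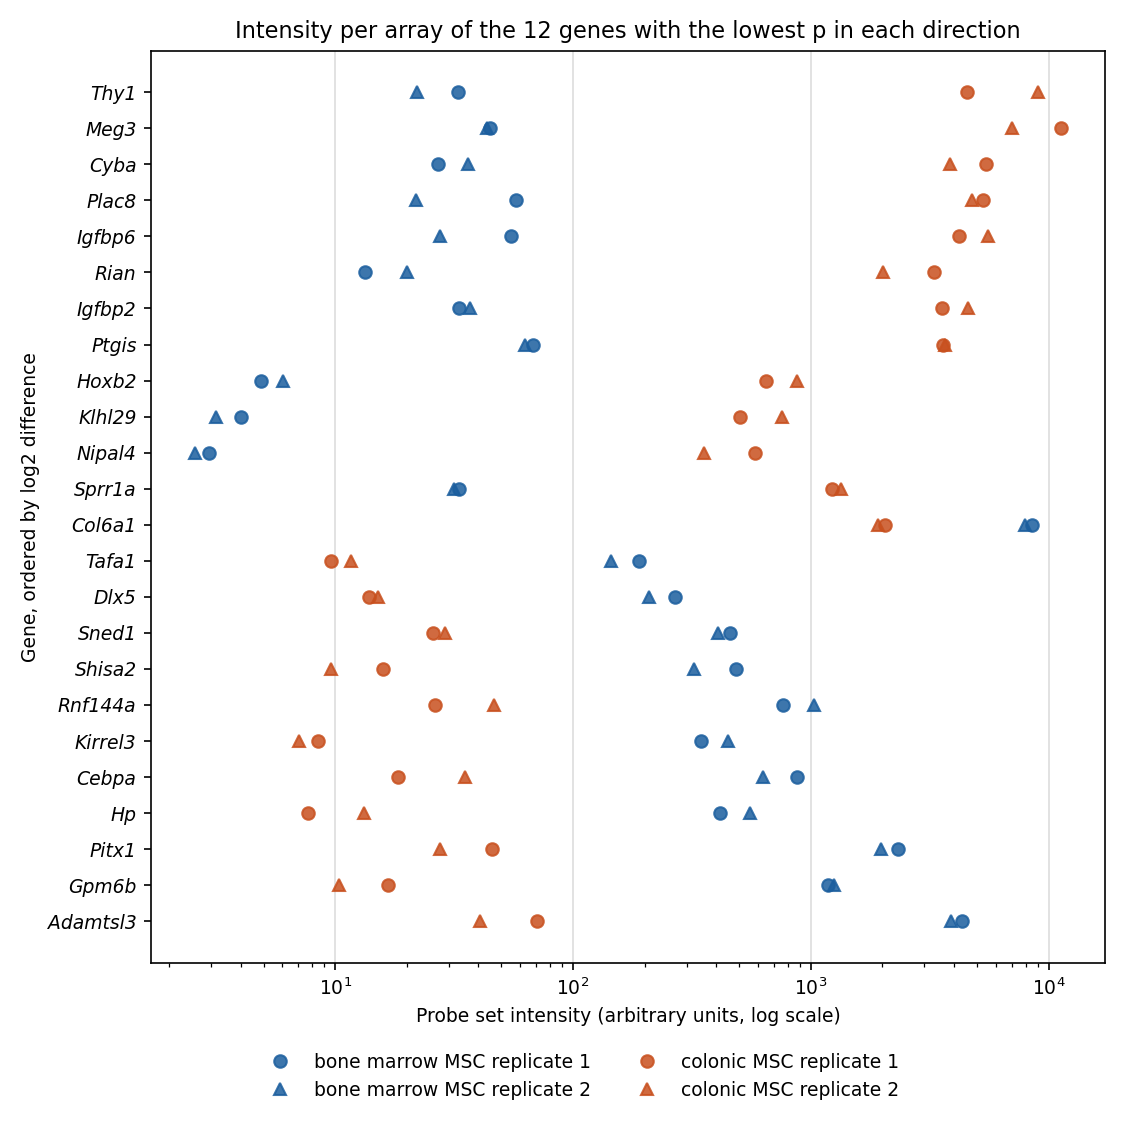
Probe set intensity (arbitrary units, log scale) of the 12 genes with the lowest p in each direction, 1 point per array, bone marrow MSC in blue and colonic MSC in orange, circles for replicate 1 and triangles for replicate 2. The tissues do not overlap for any gene drawn, as for Ptgis with 3602 and 3661 in colonic MSC and 68.0 and 62.6 in bone marrow MSC.

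With limma over 12920 genes, 0 genes passed an adjusted p of 0.05, and 775 genes had an unadjusted p below 0.05, against 646 that chance alone would give. The count of 0 lay at the edge of the threshold, and it was 13 with quantile normalization, 17 with median centring, 15 with a pseudocount of 1, 15 with a filter at the 60th percentile, 12 with the mean of probe sets, 13 without an intensity trend, 15 with robust eBayes and 33 without colonic replicate 1. It stayed 0 under the other alternatives. The smallest adjusted p was 0.0502, shared by 15 genes that include Thy1, Meg3, Pitx1 and Adamtsl3, so none of the genes named here passed the threshold over all genes. Below an adjusted p of 0.1 lay 49 genes, 33 higher and 16 lower in colonic MSC, all differing by at least 2-fold. That count became 0 without bone marrow replicate 1 and 0 without bone marrow replicate 2, and 92 and 156 without colonic replicate 1 and 2. In 120 genes, 74 higher and 46 lower in colonic MSC, the closest arrays of the tissues were at least 4-fold apart, a description chosen after seeing the data. Dividing the same arrays in the other ways possible gave 38 and 19 such genes. With limma, replicates 1 against replicates 2 gave 688 genes with an unadjusted p below 0.05 and the remaining division 344. Without overlap were 4330 genes between tissues (33.5%, with 33.3% expected by chance), 4861 and 3727. A mean difference of at least 2-fold was found in 1166 genes between tissues, 1017 and 841, and closest arrays at least 2-fold apart in 347, 161 and 122.

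Of 18 measured surface markers of MSC 0 passed over all genes and 2 were higher in colonic MSC when adjusted over the list alone, Thy1 and the sialomucin Cd34 (14.6 ± 10.5 and 3158 ± 1584, SD, n = 2). Here and below, adjustment over the list alone is not controlled across lists, so genes named by it are leads and not established differences. Mcam had intensities of 328 and 48.7 in bone marrow and 1717 and 1704 in colon, and Pdgfra 1609 and 2493 against 492 and 743, neither past either threshold, with a log2 difference as small as -0.42 in another probe set of Pdgfra. The integrin gene Itgav lay between 8393 and 8924 on all 4 arrays. As a set the list did not pass limma's camera test (adjusted p = 0.0762, median log2 difference 0.37), although without bone marrow replicate 1 or colonic replicate 2 it did (0.0165 and 0.0209), and without colonic replicate 1 the value was 0.786.

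Macrophage and monocyte markers had 13 members above the filter and 0 past either threshold (camera adjusted p = 0.932, with a median of -0.04, a mean of 0.14 and a negative test direction). Lyz2, the lysozyme of myeloid cells, ranged from 31.7 to 1589, highest in bone marrow replicate 1, and Cd53 reached 1333 in colonic replicate 2 against 155 in colonic replicate 1. Lymphoid, granulocyte and erythroid markers left 2 members for measurement, Mpo and Ms4a1, with log2 differences of 0.16 and 0.19. Intestinal epithelial markers had 10 members and 0 past either threshold (camera adjusted p = 0.289, median -0.10), and the value without colonic replicate 1 was 0.00221, toward bone marrow. The keratin gene Krt19 was at 6223 and 5083 in bone marrow MSC and at 1890 and 105 in colonic MSC. Krt20 was at 889 in colonic replicate 1 alone, against at most 29.4 elsewhere. Among 6 endothelial markers 0 passed either threshold (camera adjusted p = 0.0605, median 0.33, and 0.0399 without colonic replicate 2). Kdr was at 31.9 and 18.5 in bone marrow and 91.1 and 68.9 in colon. Enteric glia, neuron and interstitial cell of Cajal markers had 5 members and 0 past either threshold (camera adjusted p = 0.932, with a median of 0.39, a mean of 0.19 and a negative test direction). Uchl1 was at 814 in colonic replicate 1 against 100 in colonic replicate 2.

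Smooth muscle contractile genes ranked toward colonic MSC by camera with its preset correlation (adjusted p = 1.26e-04) but not once that was estimated (adjusted p = 0.748 with an estimated correlation). The estimate rests on 2 residual degrees of freedom, so it cannot decide whether the list differs. Bone marrow replicate 2 and colonic replicate 1 carried the difference, the list means per array being 0.04 and -1.16 in bone marrow and 1.00 and 0.11 in colon around each gene's mean. All 14 measured members had positive log2 differences, with a median of 0.53, and 0 passed either threshold singly. Acta2, smooth muscle actin, was near the top of the range everywhere (16513 and 15980 in bone marrow, 17010 and 16801 in colon). Actg2, the enteric smooth muscle actin, stood at 8048 ± 1011 and 11908 ± 481 (SD, n = 2), and Mylk, the myosin light chain kinase gene, at 4745 ± 863 and 9657 ± 2296 (SD, n = 2), with a log2 difference as small as 0.50 in another of its probe sets. Cnn1, calponin, was at 33.0 in bone marrow replicate 2 and between 8477 and 11529 on the other arrays, while the desmin gene Des and Myh11 reached 2379 and 1123 in colonic replicate 1 alone. The mean log2 difference of the list, 1.11, was 0.51 without bone marrow replicate 2 (camera adjusted p = 0.0179), 0.66 without colonic replicate 1 and 1.71 without bone marrow replicate 1.

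Genes of bone and fat formation included some of the clearest bone marrow signals. For osteogenic genes, 0 of 10 measured members passed over all genes and 1 was lower in colonic MSC when adjusted over the list alone, Dlx5, at 239 ± 41.0 and 14.5 ± 0.841 (SD, n = 2). Sp7, the osterix gene, had intensities of 1629 and 137 in bone marrow and 51.2 and 53.1 in colon, and Sparc differed by 0.16 on the log2 scale. As a set the osteogenic genes had a camera adjusted p of 0.236 (median -0.04), and 0.0112 without bone marrow replicate 2. Of 15 adipogenic genes 0 passed over all genes and 2 were lower in colonic MSC when adjusted over the list alone. These were Cebpa and the fatty acid binding protein gene Fabp4, at 751 ± 171 and 5029 ± 181 (SD, n = 2) in bone marrow and at 26.7 ± 11.9 and 286 ± 246 (SD, n = 2) in colon. Pparg, the nuclear receptor of fat cell formation, had 2782 and 4520 in bone marrow and 657 and 2340 in colon. For the adipogenic list the camera adjusted p was 0.0116 (median -0.21), 0.748 with an estimated correlation, and 0.113 without bone marrow replicate 2. Of 9 chondrogenic genes 0 passed either threshold (camera adjusted p = 0.695, median -0.01), and Sox9 was at 323 and 96.5 in bone marrow and 63.8 and 21.1 in colon.

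Transcription factors that record body position included some of the Hox genes ranked toward colonic MSC. Of 16 anterior and central Hox genes 0 passed over all genes and 4 were higher in colonic MSC when adjusted over the list alone, namely Hoxb2, Hoxb3, Hoxb4 and Hoxb6. Hoxb2 was at 4.87 and 6.02 in bone marrow MSC and 647 and 873 in colonic MSC, and Hoxb6 at 4.04 and 4.92 against 201 and 535. Among 11 posterior Hox genes 0 passed over all genes and 1 was higher in colonic MSC when adjusted over the list alone, Hoxd10, with a log2 difference of 5.21 ± 0.67 (SE), while Hoxc9 had -2.75 ± 0.93 (SE) and did not pass. The camera adjusted p was 0.0806 for the anterior and central list (median 0.40, and 0.0458 without colonic replicate 2) and 0.481 for the posterior list (median 0.10). Gut mesenchyme transcription factors and Hedgehog targets had 12 measured members, of which 0 passed over all genes and 1 was higher in colonic MSC when adjusted over the list alone. That gene, Foxf1, a forkhead factor of visceral mesenchyme, had intensities of 39.8 and 31.9 in bone marrow and 1566 and 1188 in colon, and a log2 difference of 1.51 in its other probe set, as Hoxb3 had 1.63 in its own. Ptch1, the Hedgehog receptor, had 2389 and 2756 in bone marrow and 1143 and 1323 in colon, and the list as a whole had a camera adjusted p of 0.783 (median 0.10).

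**Figure D2:**
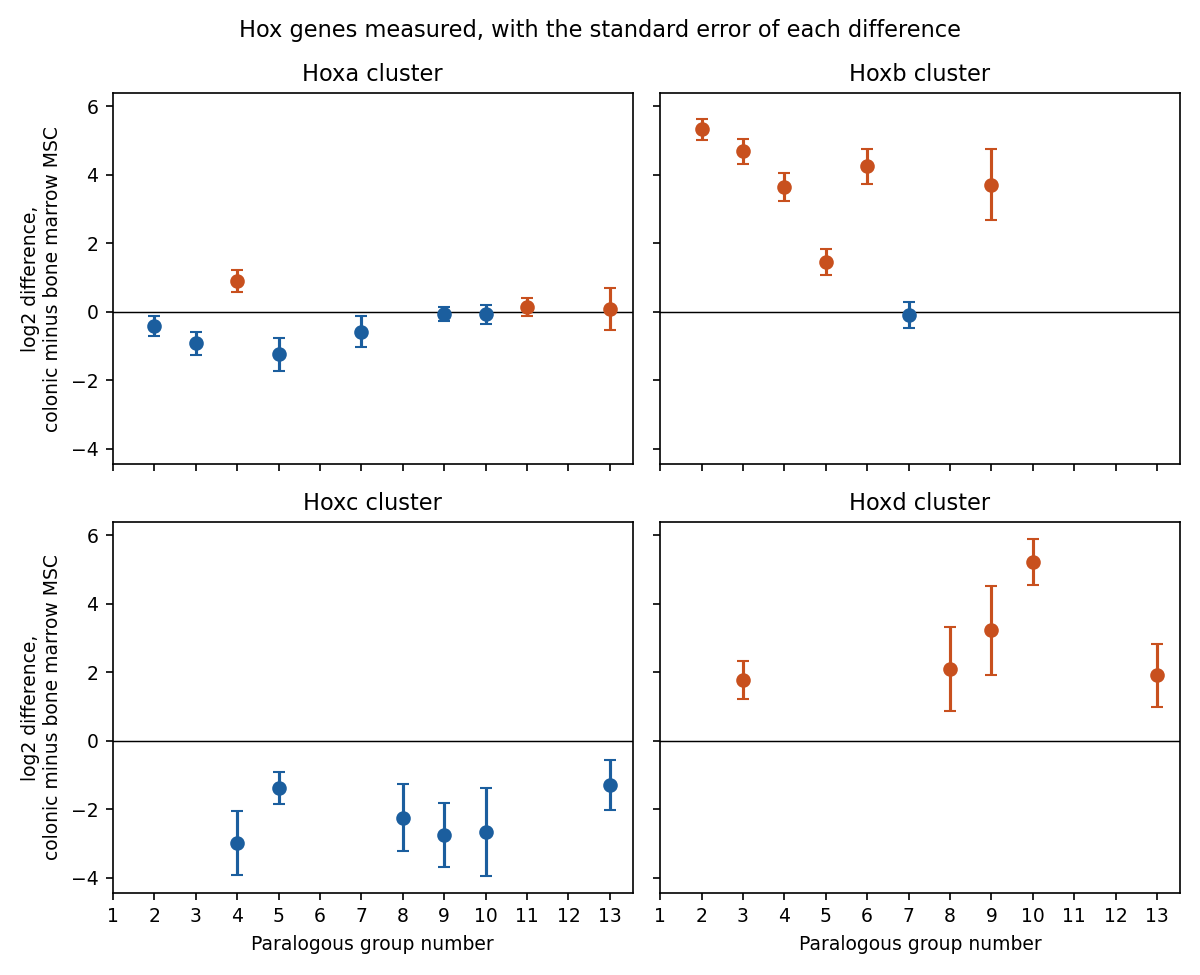
Log2 difference, colonic minus bone marrow MSC, of each measured Hox gene by paralogous group number, 1 panel per cluster, with bars for the standard error from limma (2 arrays per tissue), orange above 0 and blue below. Differences in the Hoxb cluster reach 5.33 (Hoxb2), and all 6 measured Hoxc genes lie below 0.

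Of 14 measured bone marrow niche factors 0 passed over all genes and 3 were lower in colonic MSC when adjusted over the list alone, namely Angpt1, the ligand of the receptor Tek, at 1525 and 498 in bone marrow and 13.3 and 1 in colon, the matricellular gene Ccn3, and the forkhead gene Foxc1. Cxcl12, the chemokine that retains blood stem cells, was at 11416 and 11205 in bone marrow and at 12778 in colonic replicate 2, but at 1417 in colonic replicate 1. Igf1 went the other way, with 28.8 and 77.2 in bone marrow and 1228 and 241 in colon. Over the niche list camera gave an adjusted p of 0.0278 (median -0.58) and 0.748 with an estimated correlation. Without bone marrow replicate 1, bone marrow replicate 2 or colonic replicate 2 it was 0.0848, 0.0713 and 0.0667, and the mean log2 difference of -0.87 was -0.56 without colonic replicate 2.

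Of 17 measured members of the prostaglandin and eicosanoid pathway 0 passed over all genes, and adjusted over the list alone 4 were higher and 1 was lower. Ptgs2, the inducible cyclooxygenase known from work on colonic MSC, was at 1618 ± 423 (SD, n = 2) in bone marrow and 7910 ± 678 (SD, n = 2) in colon, a log2 difference of 2.30 ± 0.24 (SE, adjusted p = 0.0991 over all genes). Pla2g4a, the phospholipase that releases arachidonic acid, was at 2632 ± 387 and 7140 ± 663 (SD, n = 2), and the others higher were Ptgis and the thromboxane synthase gene Tbxas1. Slco2a1, the prostaglandin transporter, was the lower gene, at 6895 ± 1340 and 2220 ± 610 (SD, n = 2). Ptges, a prostaglandin E synthase gene, varied within each tissue, with 246 ± 311 (SD, n = 2) in bone marrow and 381 ± 518 (SD, n = 2) in colon. As a set the list had a camera adjusted p of 0.0499 (median 0.21) and 0.748 with an estimated correlation. Without bone marrow replicate 2, colonic replicate 1 or colonic replicate 2 it was 0.137, 0.0571 and 0.136, and the mean log2 difference of 0.69 was 0.39 without bone marrow replicate 2.

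Of 23 Wnt ligands, antagonists and targets 0 passed over all genes and 3 were lower in colonic MSC when adjusted over the list alone. The Wnt antagonist Sfrp2 was at 586 and 3702 in bone marrow and 1.73 and 14.9 in colon. The others were the Wnt agonist Rspo2 (7899 and 2507 against 160 and 94.0) and Sfrp4 (226 and 488 against 26.2 and 19.2). The other probe set of Rspo2 had a log2 difference of -0.17. Dkk2 had 1 and 23.0 in bone marrow and 1626 and 125 in colon and did not pass. The list had a camera adjusted p of 0.285 (median -0.22), with 0.00721 without colonic replicate 1 and 0.0337 without bone marrow replicate 2. BMP and TGF-beta ligands, antagonists and targets had 19 members and 0 past either threshold (camera adjusted p = 0.695, median 0.02). Bmp4 was at 1546 and 1136 in bone marrow and 134 and 20.6 in colon, and the BMP antagonist Grem1 at 149 and 781 against 3175 and 2181. Among 26 growth and angiogenic factors 0 passed over all genes and 1, Angpt1, was lower in colonic MSC when adjusted over the list alone (camera adjusted p = 0.932, with a median of 2.86e-05, a mean of -0.20 and a positive test direction). Vegfa was at 2665 and 3448 against 5020 and 4239.

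Of 21 chemokines and cytokines 0 passed over all genes and 2 were lower in colonic MSC when adjusted over the list alone, Ccl7 at 492 ± 152 and 80.6 ± 18.2 (SD, n = 2) and Ccl9 at 2003 ± 200 and 162 ± 137 (SD, n = 2), with a log2 difference of -2.07 in the other probe set of Ccl9. Ccl2, the monocyte chemoattractant, had 650 and 475 in bone marrow and 183 and 122 in colon. That list had a camera adjusted p of 0.285, with a median of 0.08, a mean of -0.36 and a negative test direction, and the value was 2.69e-04 with 9 members left by a filter at the 60th percentile. Toll-like receptor and NOD signalling had 17 members and 0 past either threshold (camera adjusted p = 0.333, with a median of 0.05, a mean of -0.20 and a negative test direction), with Tlr2 at 459 and 326 in bone marrow and 87.5 and 37.0 in colon.

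Of 21 collagens 0 passed over all genes, and adjusted over the list alone 2 were higher, the basement membrane chains Col4a2 and Col4a1, and 3 were lower in colonic MSC, Col6a1, Col6a2 and Col8a1. Col6a2 was at 6999 and 5317 in bone marrow and 1048 and 204 in colon, whereas the chain gene Col6a3 had a log2 difference of 0.13 ± 0.12 (SE). Col1a2, a chain of type I collagen, differed by 0.03 ± 0.07 (SE) on the log2 scale. The camera adjusted p of the collagens was 0.783, with a median of 0.01, a mean of -0.27 and a negative test direction. Matrix proteases and inhibitors had 19 members and 0 past either threshold (camera adjusted p = 0.120, median 0.36), and without bone marrow replicate 1 or colonic replicate 2 the value was 0.0268 and 0.0283. Plaur, the urokinase receptor gene, was at 2254 and 2164 in bone marrow and 4558 and 3331 in colon.

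Interferon-stimulated and antigen presentation genes ranked toward colonic MSC by camera with its preset correlation (adjusted p = 1.26e-04, median 0.72) but not once that was estimated (adjusted p = 0.748 with an estimated correlation). Of 22 measured members 0 passed over all genes and 2 were higher in colonic MSC when adjusted over the list alone, Usp18, a protease that removes ISG15, at 13.5 ± 0.799 and 203 ± 82.3 (SD, n = 2), and the interferon regulatory factor Irf7, at 61.9 ± 5.21 and 263 ± 39.1 (SD, n = 2). In 10 members both colonic arrays lay above both bone marrow arrays, among them the viral RNA sensor gene Ifih1, and in 0 members both lay below. Over all 12920 genes both lay above in 2373 and below in 1957. The list means per array were -0.15 and -0.67 in bone marrow and 0.21 and 0.62 in colon. Bone marrow replicate 2 and colonic replicate 2 thus carried much of the difference. The class I genes B2m, H2-D1 and H2-K1 had log2 differences of 0.17, -0.11 and -0.07.

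Imprinted and oncofetal genes likewise ranked toward colonic MSC by camera with its preset correlation (adjusted p = 7.57e-04, median 0.49) but not once that was estimated (adjusted p = 0.748 with an estimated correlation). Of 13 measured members 0 passed over all genes, and adjusted over the list alone 5 were higher and 1 was lower. Meg3 and Peg3, an imprinted zinc finger gene, led, the latter with a log2 difference of 5.43 ± 0.44 (SE) and of 0.30 in its other probe set. Igf2bp1, an RNA binding protein of fetal tissues, was at 19.9 ± 9.39 and 186 ± 29.7 (SD, n = 2), a log2 difference of 2.59 ± 0.33 (SE, adjusted p = 0.151 over all genes). Ndn, a growth suppressor gene, was at 2774 and 1355 in bone marrow and 6643 and 8355 in colon, Hmga2 differed by 0.57, and Mest was the lower gene, at -1.58 ± 0.26 (SE). Probe sets of Meg3 past the filter differed in size, with log2 differences between 0.09 and 7.77 over 11 probe sets.

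Cell cycle genes split the colonic lines from each other more than the tissues. Of 30 measured members 0 passed either threshold, and the camera test placed the list lower in colonic MSC (adjusted p = 0.00248, median -0.42, and 0.804 with an estimated correlation). Mki67, the proliferation antigen, was at 1657 in colonic replicate 1 and 6348 in colonic replicate 2, with 3494 and 5309 in bone marrow, and Cdk1 at 4095 and 11364 with 9962 and 9720. Without colonic replicate 1 the list was higher in colonic MSC (mean log2 difference 0.32, camera adjusted p = 9.52e-05), and without bone marrow replicate 2 its adjusted p was 0.0753. Of 16 cell cycle inhibitors and p53 pathway genes 0 passed either threshold (camera adjusted p = 0.783, median 0.07). Cdkn1a, the p21 inhibitor, was at 20264 in colonic replicate 1, the highest intensity on that array, and at 5824 in colonic replicate 2, with 6378 and 436 in bone marrow.

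**Figure D3:**
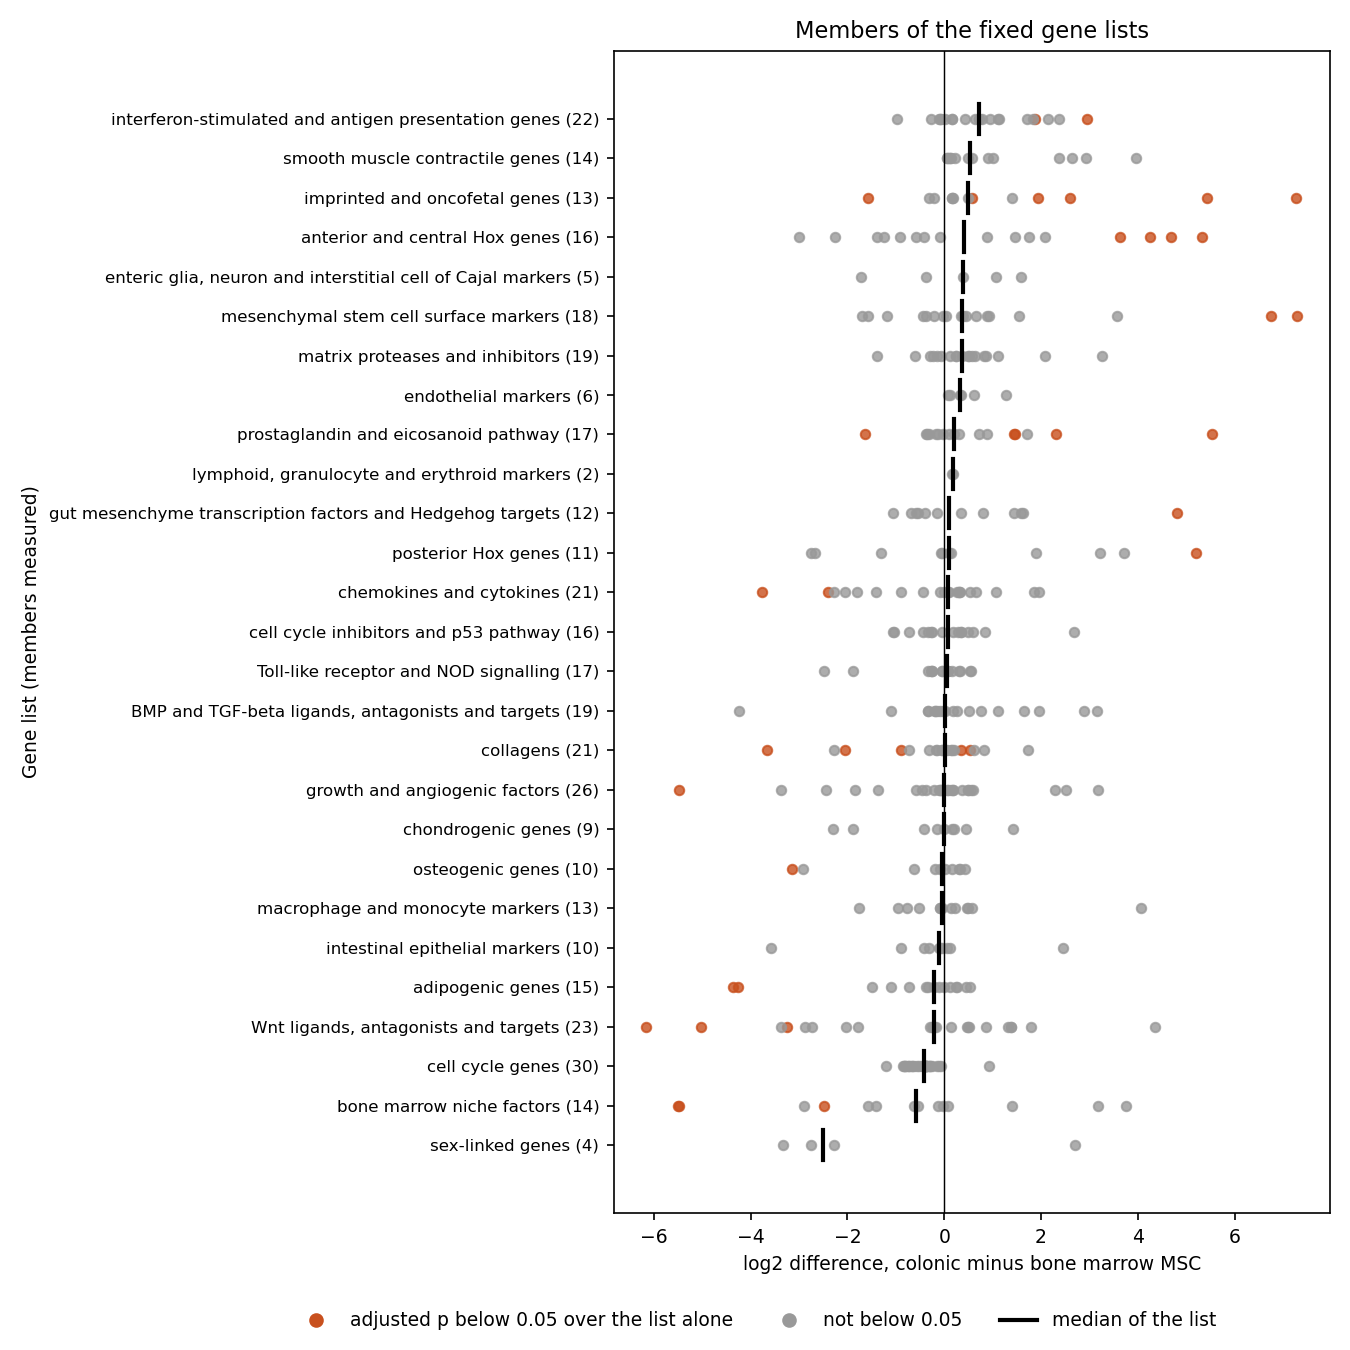
Log2 difference, colonic minus bone marrow MSC, of every measured member of the 27 gene lists, 1 point per gene, orange where the limma adjusted p over the list alone was below 0.05 and grey otherwise, with a black bar at the list median. Medians run from -2.51 for the sex-linked genes to 0.72 for the interferon list, and single genes in lists with medians near 0, such as Foxf1 at 4.80, lie far from them.

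**Figure D4:**
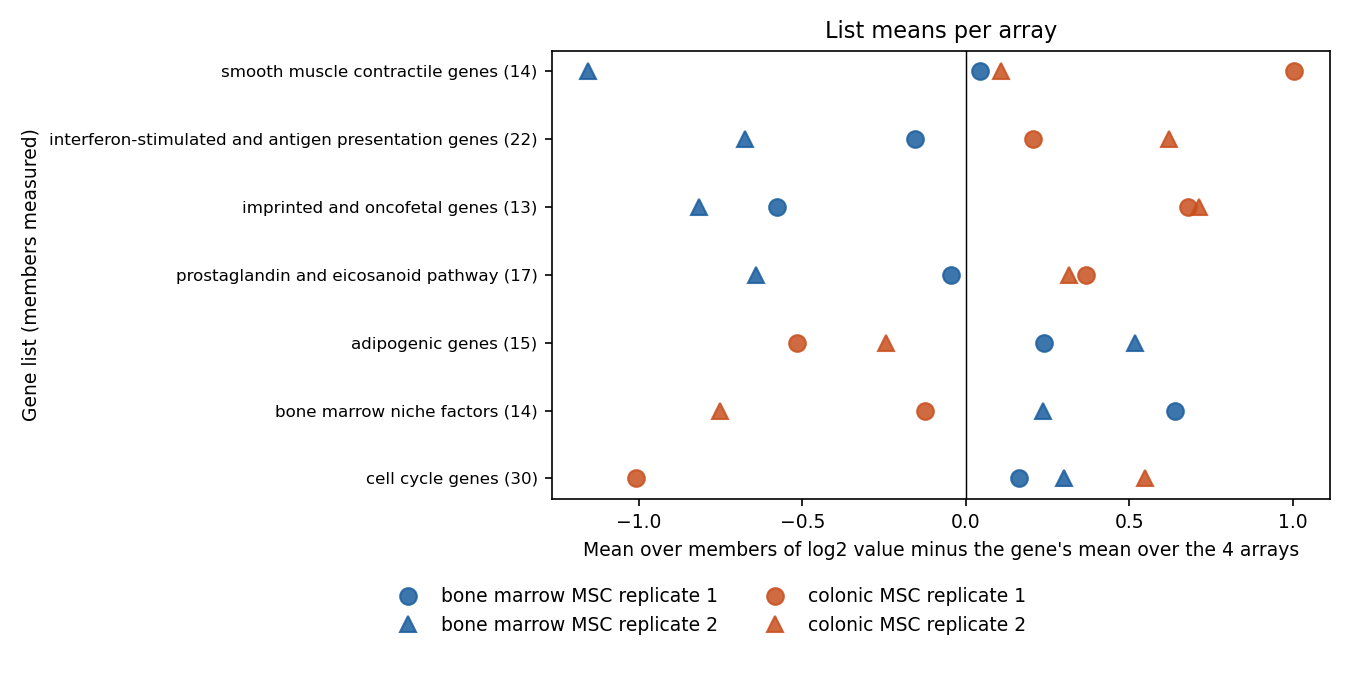
Mean over list members of the log2 value minus each gene's mean over the 4 arrays, 1 point per array, for the 7 lists past the camera threshold with the preset correlation, colours and symbols standing for tissue and replicate (bone marrow blue, colon orange, circles for replicate 1). Colonic replicate 1 alone is low for cell cycle genes (-1.01) and bone marrow replicate 2 alone is low for smooth muscle genes (-1.16).

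Sex-linked genes set 1 colonic line apart. Eif2s3y, Kdm5d and Uty, which are on the Y chromosome, had intensities of 11.0, 3.60 and 10.1 in colonic replicate 2, against 1656, 369 and 461 in colonic replicate 1, while in bone marrow MSC the lowest were 1970, 530 and 476. Xist, the RNA of the inactive X chromosome, was at 2396 in colonic replicate 2 and at most 39.8 on the other arrays. Of the 4 measured members of this list 0 passed either threshold between tissues, with a median log2 difference of -2.51, and the list was too short for the set test.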

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

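The counts at an adjusted p below 0.1 and of genes at least 4-fold apart were recomputed by settings chosen after seeing the data, and the other alternatives were fixed beforehand. The smallest adjusted p of limma, 0.0502, lay close to the threshold, and small changes in processing moved genes across it. The count of genes past 0.05, 0 as reported, was 13 with quantile normalization, 17 with median centring, 15 with a pseudocount of 1, 15 with a filter at the 60th percentile, 12 with the mean of probe sets, 13 without an intensity trend and 15 with robust eBayes. All of these genes were among the 49 below 0.1 as reported, and all differed by at least 2-fold, so that the count with the 2-fold rule was the same under each. It was 0 with the pseudocount at the table median, without a filter, with the replicate number as a block and for each probe set separately. Leaving out 1 array gave 0 to 33 genes, the 33 without colonic replicate 1, and 14 of these were among the 49. The unadjusted count under 0.05 was 775. The count below 0.1, 49 as reported, was 31 with the filter at the 60th percentile, 33 with the pseudocount at the table median, 0 with the replicate block between 33 and 51 with the other settings and 53 probe sets where each was tested separately, and 0 to 156 with 1 array left out, of which 44 of the 156 (without colonic replicate 2) were among the 49. The cause of these moves was not tested. The 120 genes whose arrays lay at least 4-fold apart became 77 with the filter at the 60th percentile, which tests fewer genes, 183 for separate probe sets, and 216 to 356 with 1 array left out, where fewer arrays have to be apart.

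The 24 genes named first gave 327 values under the alternatives, of which 0 had another sign and 105 an adjusted p below 0.05, and the smallest log2 difference among them was 1.76 in size. These genes were picked by p from the same arrays, and the tissues did not overlap for any of them. The kept sign was therefore largely fixed in advance and does not show that the differences are stable. The other 97 named genes gave 1330 values, of which 8 had another sign, none of them past the threshold, and 15 an adjusted p below 0.05.

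Of the gene lists, 7 passed with camera as preset, 0 with an estimated correlation and 1, the imprinted list, with fry (adjusted p = 0.0217). The adjusted p with an estimated correlation was 0.748 for the smooth muscle, adipogenic, niche, prostaglandin, interferon and imprinted lists and 0.804 for cell cycle genes. Adjustment tied the lists at 0.748, the smallest value reached. Their unadjusted camera p ran from 0.0536 (imprinted) to 0.282 (smooth muscle). With fry the adjusted p was 0.517 for smooth muscle genes, 0.277 for the adipogenic, prostaglandin and interferon lists, 0.304 for niche factors and 0.874 for cell cycle genes. Without regard to direction, fry gave 12 lists below 0.05. The niche list stood at 0.0564 without a filter, 0.0952 with the filter at the 60th percentile and 0.0626 with the replicate block. The prostaglandin list stood at 0.0541 with the pseudocount at the table median, 0.0750 without a filter, 0.0747 with the mean of probe sets, 0.0555 without an intensity trend and 0.0787 with the replicate block. With the filter at the 60th percentile, lists that did not pass in the main setting came to 0.0388 (MSC surface markers), 0.0445 (Wnt) and 2.69e-04 (chemokines). With 1 array left out, the adjusted p ran from 0.0165 to 0.786 for MSC surface markers, from 0.00221 to 0.847 for epithelial, 0.0399 to 0.374 for endothelial, 0.0112 to 0.846 for osteogenic, 0.00348 to 0.113 for adipogenic, 0.0458 to 0.179 for anterior Hox, 8.56e-04 to 0.0848 for niche, 0.0268 to 0.137 for prostaglandin, 0.00721 to 0.924 for Wnt and 0.0268 to 0.740 for protease lists. For cell cycle genes it ran from 4.06e-21 (without colonic replicate 2) to 0.0753, and without colonic replicate 1 the direction turned (9.52e-05). With camera at its preset correlation, the smooth muscle, interferon and imprinted lists passed with each array left out. That does not show a stable difference, since the same test called the cell cycle list in opposite directions. For smooth muscle genes the list means of bone marrow replicate 1 (0.04) and colonic replicate 2 (0.11) lay close together.

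The labels number the replicates 1 and 2 in both tissues without naming a shared animal or day, and the deviations of same-numbered arrays correlated with r = 0.107 across 12920 genes over only 2 pairs, so the numbers were not taken to pair the lines. The replicate block changed no other list call. Signals near the floor limit what low genes can show, since no detection call was used.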

Other observations

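The tests of the Meg3 region, of the cell cycle list and of the sex-linked genes were written after the values were seen, except that of a mislabelled line, whose comparison with the bone marrow arrays was added afterwards. Grouping the Hox genes by chromosomal cluster, rather than by anterior and posterior members, was also chosen after the values were seen. In the Hoxb cluster 6 of 7 measured genes had both colonic arrays above both bone marrow arrays, with a median log2 difference of 3.71, Hoxb7 being the exception at -0.09. In the Hoxc cluster 6 of 6 genes had both colonic arrays below, with a median of -2.46, but colonic replicate 2 carried much of the size, as for Hoxc4 at 156 in colonic replicate 1 and 14.4 in colonic replicate 2, and without that array the median was -1.13. In the Hoxd cluster 4 of 5 were above, with a median of 2.09. That median was 3.63 without bone marrow replicate 1 and 1.83 without bone marrow replicate 2. Hoxd10 went from 25.9 and 40.8 in bone marrow to 941 and 3098 in colon. The 9 Hoxa genes had a median of -0.07, and Hoxa9, Hoxa10 and Hoxa11 lay between 1597 and 3198 on all 4 arrays. Camera placed the Hoxb, Hoxc and Hoxd clusters apart from other genes (adjusted p = 7.9e-11, 1.98e-05 and 2.47e-05 over 4 clusters), and with an estimated correlation the adjusted p was 0.117, 0.249 and 0.117. These p-values describe groups picked from the same values.

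Below an adjusted p of 0.1 lay further genes outside the fixed lists and the named set, chosen here after their values were seen. Dcn, decorin, a small proteoglycan of connective tissue, was at 43.5 ± 39.9 (SD, n = 2) in bone marrow and 4298 ± 64.1 (SD, n = 2) in colon. C1qtnf3, an adipokine gene, had a log2 difference of 6.93 ± 0.60 (SE), the hormone gene Cck 5.82 ± 0.51 (SE), the homeobox gene Irx1 4.98 ± 0.38 (SE), and Dmd, the dystrophin gene, 4.48 ± 0.47 (SE). The aldehyde dehydrogenase gene Aldh1a3 had 4.61 ± 0.41 (SE), the alcohol dehydrogenase gene Adh7 -5.02 ± 0.49 (SE) and the homeobox gene Lhx9 -2.34 ± 0.24 (SE).

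The noncoding RNAs Meg3, Rian and Mirg, neighbours in 1 imprinted domain, were all higher in both colonic lines, with median log2 differences of 3.88, 3.61 and 1.97 over their probe sets. A single cross-hybridising probe set is argued against by 15 of 16 probe sets past the filter with both colonic arrays above both bone marrow arrays. Some of these passed the filter only because the colonic arrays were high, so that share and the medians are biased upward. The smallest gap among the 15 was 0.05. Separate probe sets of each transcript showed the difference, with highest log2 differences of 7.77 (Meg3), 6.42 (Rian) and 2.62 (Mirg). Scaling of the arrays is argued against by their log2 medians, which lay within 0.04 of each other. Quantile normalization and median centring could therefore move little, and the difference of Meg3 stayed at least 7.23 under both. A change during culture, which imprinted domains may undergo, and a difference of tissue cannot be told apart with 2 lines per tissue, and the lines of 1 tissue differed by at most 0.683 on the log2 scale in the probe set standing for Meg3 and by up to 1.52 among all 16. A difference between tissues therefore stays open as a hypothesis.

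Cell cycle genes were lower in the colonic group only through replicate 1. Without that array the mean log2 difference of the list was 0.315 toward colonic MSC, consistent with 1 line having low cell cycle transcripts. A difference shared by the colonic lines is argued against, since 1 of 30 members had both colonic arrays below both bone marrow arrays. Whether passage, confluence or the high Cdkn1a of that line goes with it is not tested here.

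Colonic replicate 2 combined high Xist with Y-linked genes near the floor. In each measured Y-linked gene it had at most 0.0219 of the intensity of the lowest other array, and Xist, near the floor on the other arrays, was at least 60.2 times the highest of these, consistent with a line from a female mouse among male ones. Loss of the Y chromosome in a male line is argued against by the same 60.2, a lower bound. For a mislabelled bone marrow line, the bound set beforehand was under 50% of genes nearer to colonic replicate 1. The genes were picked from the other arrays, and the share was 46.6% of 343 genes, which meets that bound. The exact binomial interval, 41.3 to 52.1%, treats genes of 1 array as independent and does not measure how far lines vary. Held out in the same way, bone marrow replicate 1 lay nearer to its own tissue in only 48.9% of genes. The shares were 70.4% for bone marrow replicate 2 and 59.2% for colonic replicate 1. Since bone marrow replicate 1 also fell under 50%, the bound does not separate the cases. Held out likewise, the bone marrow arrays lay nearer to colonic replicate 1 in 26.7% and 19.2% of genes, below the 46.6% of colonic replicate 2. Division by tissue gave 120 genes with closest arrays at least 4-fold apart, against 38 and 19 for the other divisions. That measure was chosen after seeing the data. By contrast, 4330 genes did not overlap between tissues, fewer than the 4861 between replicates 1 and replicates 2, so these counts do not decide on a wrong label. Across all probe sets, colonic replicate 2 correlated more with bone marrow replicate 1 (r = 0.970) than with colonic replicate 1 (r = 0.967). A wrong label stays open because only 2 lines per tissue show how far lines of 1 tissue vary.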
